A study of Homo sapiens with 2 samples.

How the data were processed

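RNA labelled with Cy5 was hybridised to 2 one-colour miRNA arrays, 1 for Pg-infected and 1 for non-infected THP-1 macrophage-like cells; per the labels' protocols the 3D-Gene labelling kit was used. The deposited file of each array holds a spot median intensity and a local background median intensity for each of 3200 spots. Per the file headers the spot was read at 635 nm with 3 scanner gains, whose readings were joined by least squares; the scanner software is not given in the sources used here. All spots carried the flag OK at each gain. The authors' deposited value table gives 1 normalized signal per miRNA on a linear scale. How it was made is not stated, and it was worked out from the values. The listed signal of each array is a straight line of its spot median intensity, within a largest residual of 8.73e-06. The intercepts, 83.9 and 81.8, equal the means of the blank spots after the top and bottom 5% were left out. The scale sets each column's median to 25, and the 590 and 589 empty cells are the probes under the detection limit described next. Values were not centred per probe, and the 2 columns run in the direction of the labels. Groups came from the treatment label, although the protocol text of the non-infected sample also describes infection, and no column of another series was present.

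The detection limit of each array was the mean plus 2 SD of 280 of the 312 blank spots, which was 85.6 on the infected and 83.4 on the non-infected array. For the main values, background was corrected with limma's normexp method (offset 50), control spots were then left out, and the 2632 miRNA probes were quantile normalized between the 2 arrays and put on the log2 scale (limma 3.58.1, R 4.3.3). With this offset a log2 difference understates the change of a dim probe. Each miRNA has 1 spot, and 16 probes target more than 1 miRNA. The plan written before the data were examined used the local background column in normexp. That column was set aside because it follows the spot signal: its Spearman correlation with the spot median was 0.95 and 0.96 across all spots of the 2 arrays. It also lay above the spot itself for 30 and 22 miRNA probes, among them let-7a-5p with a local value of 1580 around a spot of 1235. The main background was therefore estimated from the spot intensities alone, a choice made after seeing the data, and the planned version is reported among the alternatives; it changes the sign of several miRNAs.

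With 1 array per group there is no test, so no p-value was computed and miRNAs were selected by size, an absolute log2 difference of at least 1 among miRNAs detected on both arrays. Percent values are shares of probes. For a miRNA under the limit on 1 array, the bound is the brighter array's value over the higher of the lowest normalized value among detected probes and the probe's own value on the dimmer array. The median of each of 15 lists of miRNAs was set against 10000 random lists of the same size drawn from the same signal deciles; its percentile describes these 2 arrays only. A list needed at least 3 measured members. The lists, the size rule and the rule for naming miRNAs were written before the data were examined. The rule named up to 12 of the largest differences in each direction among miRNAs past the size rule with the same sign in the deposited values, which gave 6 higher and 12 lower, up to 5 per direction detected on 1 array only, up to 4 members of each list and 10 miRNAs named in advance. Members of the lists and name families beyond the rule were chosen after their values were seen. Counts by at least 1.5-fold within lists use a size fixed in advance as a second size rule, in place of a smaller size tried first. On the lists, 10 entries (1 name is on 2 lists) had no probe of that name on the array. Gene names came from a RefSeq table of GRCh38.p14 matched by symbol; as the files name no genome build, only names and overlaps of genes were taken from it.

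The steps were tested on simulated arrays for the infected against non-infected comparison, with 200 of 2632 miRNAs changed. Among miRNAs above 4 times the limit, 98.0% of the 3-fold and 100.0% of the 6-fold changes passed the size rule; among dimmer ones, 16.0% and 44.0% did. None of 1798 unchanged detected miRNAs passed. The simulated log2 noise had an SD of about 0.15, the size of spot-to-spot variation, without variation between cultures, extractions or hybridisations. On the real arrays the differences had an SD of 0.44 in the brightest of 4 equal bins by signal. This count could therefore hardly have been otherwise and gives no rate of false calls for the real arrays. The precision is limited by the number of arrays. Alternatives concerned the background correction, the offset, the scaling, the detection limit, the filter on dim probes, the size rule and the deposited values; scaling to the spike controls and random lists of early-registered miRNAs (MIMAT number below 1000) were added after seeing the data, as were bounds in the deposited values (listed value over the lowest listed value of the other array), and the local background column became an alternative then. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15.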

Results

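The series profiled microRNAs (miRNAs) from THP-1 cells, a human acute monocytic leukaemia line that takes on macrophage features after treatment with the phorbol ester PMA. The cells received 100 nM PMA for 48 h and were then infected with Pg, an agent whose abbreviation the labels do not spell out, at a multiplicity of infection of 100, or were left without infection. According to the series design, infection lasted 4 h, the agent and the vesicles already present were then taken away, and the miRNAs of interest were those in extracellular vesicles given off over the next 48 h. The titles of both samples name vesicle miRNA, whereas the extraction protocol speaks of RNA from cells, so the fraction that was hybridised rests on the titles and the design text. The treatment protocol of the non-infected sample repeats the infection step, so its group rests on its title and its treatment label. The question was which miRNAs vesicles of infected macrophages carry. There was 1 array per group, so the values below compare 2 arrays, no p-value or replicate error exists for any difference, and infection cannot be told apart from any other difference between the 2 cultures, extractions or hybridisations.

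Each array held 2632 human miRNA probes, each spotted once, and 312 blank spots. The spot median was above the detection limit for 2042 probes (77.6%) on the infected array and for 2043 probes (77.6%) on the non-infected array. The median spot intensity of detected probes was 127.0 on the infected array and 119.6 on the non-infected array, against trimmed blank means of 83.9 and 81.8, so a typical detected probe lay close to background. Spots named No Probe passed the limit too, 111 of 112 on the non-infected array, and their mean on the infected array, 91.1, was above it. All 8 spots of negative control 3 passed on both arrays, with means of 103.4 and 100.0. The other kinds of negative control spots had means under the limit. Passing the limit alone therefore does not show signal beyond non-specific background. On both arrays 1997 probes were detected, and 544 on neither. Across these 1997 miRNAs the normalized log2 intensities of the 2 arrays had a Pearson r of 0.99 and a Spearman rho of 0.99; these describe agreement across probes, which are not independent replicates. The only repeated measurement within an array was that of control spots: 8 spots each of 2 spike controls had a pooled SD of 0.11 on the log2 scale, which gives an SD of 0.15 for the difference between 2 single spots and covers spot-to-spot variation alone.

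miR-146a-5p, miR-155-5p and miR-146b-5p, miRNAs known as background to respond to bacterial ligands in monocytes and macrophages, were among the 6 miRNAs at least 2-fold higher on the infected array. miR-146a-5p (MIMAT0000449) had a spot intensity of 1404 on the infected and 444.0 on the non-infected array, a normalized fold of 2.77 and a log2 difference of 1.47. miR-155-5p (MIMAT0000646) had intensities of 2064 and 704.6, a fold of 2.60 and a log2 difference of 1.38. miR-146b-5p (MIMAT0002809) had intensities of 727.6 and 290.1, a fold of 2.25 and a log2 difference of 1.17. By gene name the miR-155 gene lies within MIR155HG and that of miR-146a within MIR3142HG. In the authors' deposited values the folds of the 3 were 3.20 for miR-146a-5p, 2.79 for miR-155-5p and 2.71 for miR-146b-5p. Each of the 3 differences was larger than the spot-to-spot SD of 0.15, and each log2 difference stayed above 1 in all 15 settings tried. These settings include the main one and those that change only the detection filter, which cannot move a single value. Replicate cultures were not measured.

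The other 3 miRNAs at least 2-fold higher were miR-3197, with a fold of 2.67, miR-3178, with a fold of 2.16, and miR-550a-5p, with a fold of 2.04. Both miR-3197 and miR-3178 were bright: their intensities were 18664 against 5910 and 19929 against 7541. miR-550a-5p had intensities of 586.7 and 252.1, and its log2 difference of 1.03 became 0.95 without background correction and 0.65 with the local background column, both under the size rule.

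Of the 1997 miRNAs detected on both arrays, 15 were at least 2-fold lower on the infected array. The most different were miR-6073 (3.80-fold lower, log2 difference -1.93), miR-6834-5p (3.75-fold, -1.91), miR-3937 (3.41-fold, -1.77), miR-4648 (3.11-fold, -1.64), miR-6131 (3.06-fold, -1.62) and miR-6778-5p (3.03-fold, -1.60). miR-4486, miR-6895-5p, miR-5008-3p, miR-670-5p, miR-6865-5p and miR-7151-3p followed, with log2 differences of -1.25, -1.20, -1.18, -1.17, -1.15 and -1.09. This order holds for the main values. miR-670-5p was at -1.97 with the blank mean subtracted and at -1.93 in the authors' deposited values. miR-6073 was at -0.80 with the local background column. By gene name several of these lie within protein-coding genes: miR-6073 in SOX6, miR-6834 in PFDN6, miR-4648 in LFNG, miR-6778 in SHMT1, miR-4486 in NAV2 and miR-6895 in KDM5C. Spot intensities ranged widely in this group, with 167.8 against 484.4 for miR-6073 and 8842 against 20893 for miR-6778-5p. All 15 stayed lower on the infected array in the 11 settings without the local background column, but 7 of them stayed at least 2-fold lower in each of these. miR-4486, miR-5008-3p, miR-6865-5p and miR-7151-3p, at -0.96, -0.98, -0.93 and -0.80, missed the size rule without scaling. With the local background column, which the original plan called for, 12 stayed lower, 6 of them at least 2-fold, and miR-6131 (3.47), miR-5008-3p (0.012) and miR-3135b (to more than 2-fold higher) turned. miR-3135b, at -1.08 in the main values, is named after its values were seen.

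**Figure D1:**
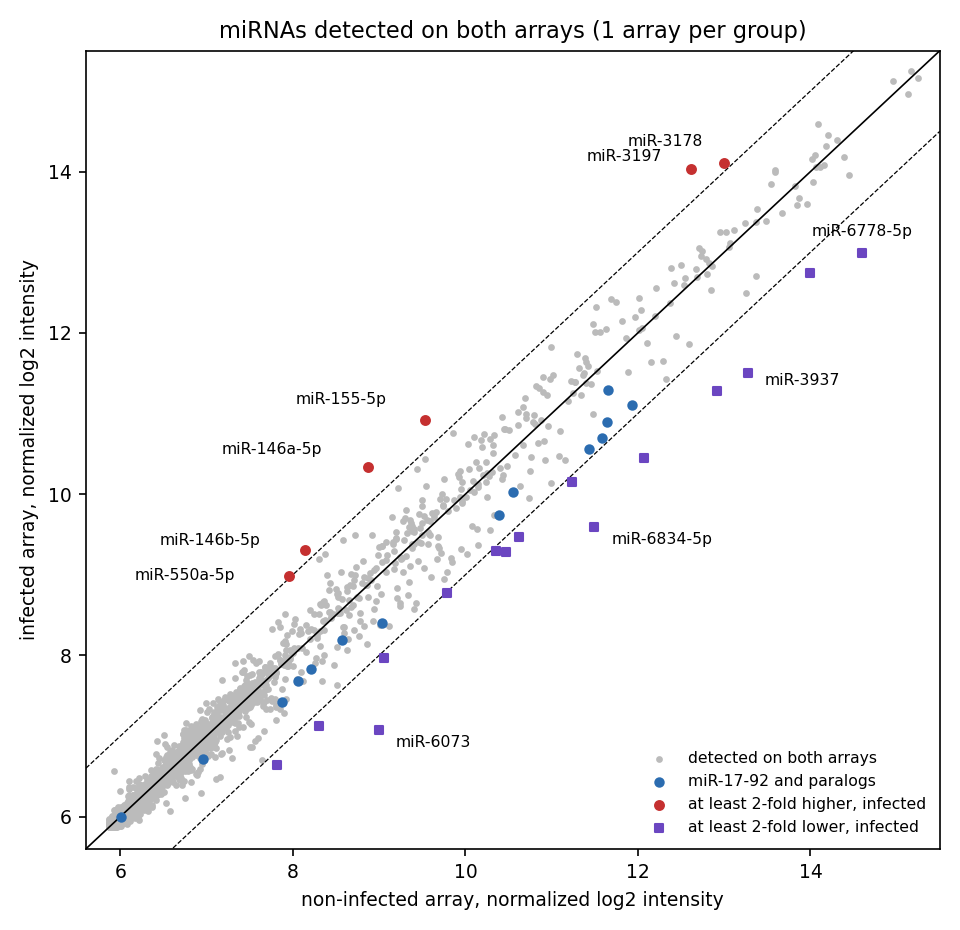
Normalized log2 intensity of the 1997 miRNAs detected on both arrays, infected array (vertical) against non-infected array (horizontal); the solid line marks equality and the dashed lines a 2-fold difference. The 6 red points are at least 2-fold higher and the 15 violet squares at least 2-fold lower on the infected array, and the 14 blue points are the miR-17-92 members and paralogs, each under the solid line.

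The 21 miRNAs past the size rule were 1.05% of those detected on both arrays, and all 21 had the same sign in the authors' deposited values. No test stands behind the size rule. The split depended on the scaling, and the total count more on the background correction. The counts of 6 higher and 15 lower became 11 and 11 with arrays centred on their medians. They were 9 and 12 with the 75th percentile or with the spike controls as the scale, and 15 and 8 without any scaling. They were 33 and 48 with the blank mean subtracted in place of the main background correction, and 31 and 54 in the authors' deposited table, where 18 and 31 of these had both values under the column median of 25. With the local background column they were 38 and 33.

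The miR-17-92 cluster and its paralogs, a group of miRNAs linked as background to proliferation and myeloid differentiation, had values below 0 in all 14 of the measured members, with miR-363-3p, a dim one, at -0.0074. Their median log2 difference was -0.49, a 1.41-fold lower signal, and none of the 10000 random lists matched on size and signal had a median as low (middle 95% of random medians, -0.098 to 0.18). Among its members miR-20a-5p had a log2 difference of -0.89, miR-20b-5p -0.88, miR-17-5p -0.83 and miR-106a-5p -0.74, and 6 of the 14 were lower by at least 1.5-fold. No member reached 2-fold in the main values. With the local background column miR-106a-5p turned to 0.73, whereas miR-17-5p, miR-20a-5p and miR-20b-5p were at -2.91, -2.31 and -1.82. The spot intensity of miR-17-5p was 2335 on the infected array and 3679 on the non-infected array, before scaling. The genes of miR-17 and miR-20a lie within MIR17HG, and those of miR-106a and miR-20b within MIR106AHG. The list median stayed negative under all 15 settings and was closest to 0, at -0.30, without scaling. Among random lists drawn from early-registered miRNAs alone (registration number below 1000) the 12 early members lay at percentile 0.945. Many members are closely related in sequence or share a transcript, so their signals are not independent. Both kinds of random lists were drawn without regard to such relations, so these comparisons may overstate how unusual the list is.

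The list of miRNAs known to respond to bacterial ligands held 19 members detected on both arrays, of which 3 were at least 2-fold higher and none at least 2-fold lower. These 3 were miR-146a-5p, miR-155-5p and miR-146b-5p; the next largest difference was that of miR-125a-5p, with a log2 difference of 0.50, which turned to -0.048 with the local background column. miR-21-5p (-0.32) had the lowest value, and it was at -2.48 with the local background column. miR-132-3p, a further member, was dim and had a log2 difference of 0.18, against 0.71 in the authors' deposited values. The median of the list was 0.056, at percentile 91.2 of matched random lists, and at percentile 99.5 for its 14 early-registered members among early-registered miRNAs. Without scaling the median was 0.21.

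Myeloid-enriched miRNAs went both ways. The list had 14 measured members, 4 of which were lower and none higher by at least 1.5-fold, 9 lower and 5 higher by any amount, with a median log2 difference of -0.17 at percentile 0.22 of matched random lists. miR-342-3p (-0.83), miR-27a-3p (-0.76), miR-142-5p (-0.61) and miR-191-5p (-0.59, turning to 0.52 with the local background column) were lower, as was miR-223-3p, the myeloid miRNA with the strongest lineage restriction in background knowledge, at -0.57. With the local background column miR-27a-3p was at -1.83 and miR-223-3p at -2.38. The opposite arm of the miR-142 hairpin, miR-142-3p, had 0.51, which turned to -0.018 with the local background column. Against early-registered miRNAs alone the 12 early members lay at percentile 6.01, inside the middle 95%, and the list median was -0.53 with the brighter miRNAs alone and -0.075 without scaling.

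The 13 miRNAs linked to phorbol ester differentiation of THP-1 cells had a median of 0.058, at percentile 83.7 of matched random lists, and at percentile 99.8 for its 10 early-registered members among early-registered miRNAs. Besides miR-155-5p, which is also on this list, the largest values were those of miR-29b-3p (0.60), miR-222-3p (0.46) and miR-29a-3p (0.40), all of which turned negative with the local background column, at -0.19, -1.94 and -0.29. With the brighter miRNAs alone the median was 0.43, and with the local background column it was -0.0001. The let-7 family, with 9 measured members between -0.28 for let-7c-5p and 0.16 for let-7i-5p (both of which changed sign with the local background column), had a median of 0.022 at percentile 42.5, and without scaling the median was 0.22. The let-7 median turned to -0.077 with the brighter miRNAs alone and to -0.091 with the local background column. The 5 members of the miR-320 family had nearly equal values, with a median of -0.35 at percentile 1.18, and miR-320a-3p was the lowest at -0.43, although miR-320b and miR-320c turned to 0.32 and 0.096 with the local background column; the probes of this family target closely related sequences, so their signals are not independent. The 41 GC-rich or repeat-like entries that are often bright on arrays had a median of 0.12 at percentile 84.1, with miR-3178 highest and miR-1268b (-0.76), miR-4454 (-0.66) and miR-7975 (-0.64) lowest.

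The 17 miRNAs associated with vesicle export in background knowledge had a median of -0.17 at percentile 0.08, and the sign turned without scaling (0.018). miR-451a (-0.66, turning to 0.18 with the local background column) and miR-4443 (-0.59) had the lowest values, and miR-1246 had -0.17, with a sign that turned under 3 scalings. Against early-registered miRNAs alone the 10 early members lay at percentile 8.46. Of the 11 members with values below 0, all but miR-4443 are also on other lists. Examples are miR-223-3p on the myeloid-enriched list, miR-320a-3p on the miR-320 list and miR-451a on the serum and erythroid list. The medians and percentiles of this list and of the lists that share its members therefore rest partly on the same probes and are not separate results.

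**Figure D2:**
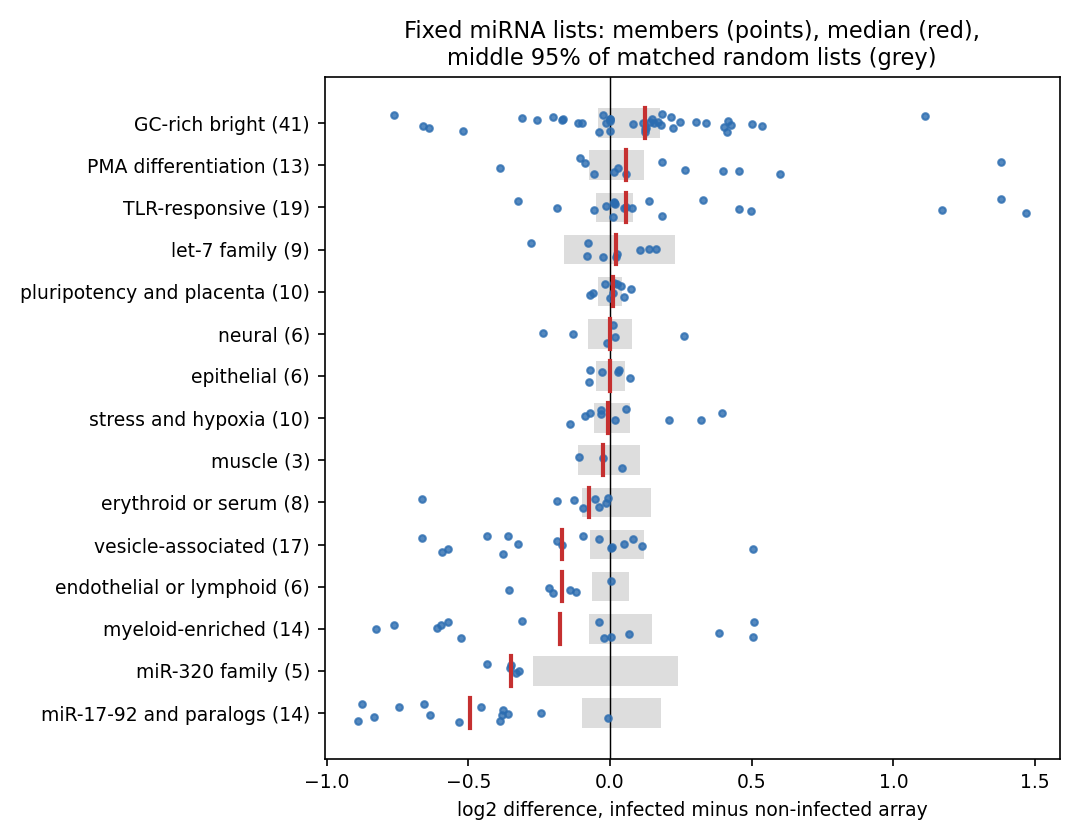
Log2 difference, infected minus non-infected array (horizontal), of the members of each fixed miRNA list detected on both arrays (points; number of members in brackets), with the list median (red line) and the middle 95% of the medians of 10000 matched random lists (grey bar). The miR-17-92 median of -0.49 and the miR-320 median of -0.35 are the lowest, and 3 points of the list responsive to bacterial ligands lie above 1.

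Lists of miRNAs typical of other sources were fixed as well. Serum and erythroid miRNAs had 8 measured members, all with values below 0 in the main values, and a median of -0.074 at percentile 5.65, which turned to 0.013 without scaling; miR-451a, at a spot intensity of 120.0 against 161.5, was the only one lower by at least 1.5-fold. Epithelial (6 measured members, median 0.00023, percentile 46.3), muscle (3, -0.025, 28.9), neural (6, 0.0018, 44.6), pluripotency and placenta (10, 0.012, 67.2) and stress and hypoxia miRNAs (10, -0.0072, 30.0) had medians within the middle 95% of their random lists. Within the last list miR-210-3p, a hypoxia-induced miRNA, had a value of -0.070, and miR-107 had 0.40, turning to -0.79 with the local background column. Most epithelial and most pluripotency and placenta members were dimmer than the means of negative control 3, 103.4 infected and 100.0 non-infected. Examples are miR-205-5p (98.4 and 98.1) and miR-372-3p (86.1 and 84.5). Values near 0 for such probes do not show a miRNA that is present and unchanged. Endothelial or lymphoid miRNAs (6) had a median of -0.17 at percentile 0.02, with miR-181a-5p at -0.36, miR-10a-5p at -0.22 and miR-126-3p at -0.14, the last turning to 0.065 with the local background column. Members of this list were dim, with spot intensities up to 155.6, and the median was -0.69 in the authors' deposited values and 0.0063 with the local background column.

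Detection on 1 array only concerned 45 miRNAs on the infected and 46 on the non-infected array. All were near the limit. The largest bound was that of miR-548bc, at least 1.20-fold higher on the infected array, followed in the other direction by miR-450a-2-3p, at least 1.16-fold higher on the non-infected array. None reached a bound of 2-fold in the main values. The spot intensity of miR-548bc was 98.0 on the infected array against a limit of 85.6, and that of miR-450a-2-3p was 92.2 on the non-infected array against a limit of 83.4. The authors' deposited values have no offset and another background correction and scaling. There the bounds were 7.29-fold for miR-548bc and 6.96-fold for miR-450a-2-3p. A bound of at least 2-fold was found for 7 miRNAs on the infected and 13 on the non-infected array. These are ratios of small blank-subtracted values, 8.17 over 1.12 and 6.90 over 0.99 for the 2 named. Both spots were dimmer than every negative control 3 spot of the same array (lowest 101.7 infected, 97.3 non-infected). The bounds therefore do not show a difference beyond non-specific signal.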

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

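All tests in this part were chosen after the results were seen. Control spots that enter no comparison differed between the arrays. The labels and files do not say what the probes named S-Probe are. Of these, 4 kinds of spots were above the limit on the infected array and had every spot on the infected array brighter than every spot on the non-infected array, with a signal over blank at least 1.5 times as high. S-Probe1014 had a mean spot intensity of 592.5 ± 19.9 (SD, n = 8 spots) on the infected and 317.8 ± 14.2 (n = 8 spots) on the non-infected array, a ratio of 2.15 over blank. The ratios were 2.34 for S-Probe28 (means of 103.2 and 90.0) and 1.53 for S-Probe22 (91.1 and 86.5), the latter 1.28 without its brightest spot. S-Probe25 gave 7.38, a ratio that rests on 1 spot of 192.1 and on non-infected spots near the limit; without that spot it was 1.53. S-Probe21 (means of 88.2 infected and 91.6 non-infected) and S-Probe23 (91.3 and 97.2) went the other way, with ratios of 0.44 and 0.48. Apart from S-Probe1014, the S-Probe kinds named here had means under those of negative control 3, 103.4 and 100.0. Their ratios are therefore ratios of small values over blank and do not show a difference beyond non-specific signal. The spike controls had ratios of 1.11 and 1.12 before scaling.

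The higher signals of miR-155-5p, miR-146a-5p and miR-146b-5p were weighed against 3 technical explanations. The smallest of the 3 log2 differences over 15 settings was 1.005, for miR-146b-5p with the local background column. The 3 were chosen by the main values, 1 of these settings, so this minimum could hardly have been low, and no conclusion is drawn from it. Settings that change only the detection filter could not move these values. Without any scaling miR-155-5p, miR-146a-5p and miR-146b-5p were at 1.58, 1.72 and 1.40. Without background correction they were at 1.35, 1.42 and 1.10, so neither step alone gave them their direction. The spots next to these probes had median log2 differences of at most 0.112 in size, which argues against a local stain or gradient. Whether the miR-146b-5p probe reads miR-146a-5p stays open: their blank-subtracted log2 differences were 0.238 apart, within 2 spot-to-spot SDs of a difference, and probe sequences were not used here. The infection that the labels name, and any other difference between the 2 preparations, could each account for the pattern, and neither was tested with 1 array per group.

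The lower signals of the miR-17-92 members and paralogs were weighed in the same way. The highest list median over the settings was -0.296, which argues against scaling alone. Against a lower signal of early-registered miRNAs, the early members lay at percentile 0.945 of random lists of such miRNAs. Those lists were drawn from a pool that holds these same members, whose signals are not independent. How much of the difference comes from that trend therefore stays open. Leaving out miR-17-3p (-0.24), the opposite arm, the 7 members outside the closely related miR-17 group had a median of -0.383, against -0.787 for the 6 members of that group, so probes of the miR-17 group reading one another would leave the former unexplained. Infection as the cause was not tested.

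The 15 miRNAs at least 2-fold lower all had registration numbers of 1000 or above. The median over these miRNAs of the median log2 difference of adjacent spots was -0.0047 (range -0.14 to 0.13), which argues against a local stain. All 15 stayed at or under -0.5 in every one of 11 settings without the local background column. The 15 were chosen by the main values, 1 of these settings, and the cutoff of -0.5 was set after the results were seen. This count could therefore hardly have failed, and no conclusion is drawn from it. Without any scaling the 15 ranged from -1.72 for miR-6834-5p to -0.75 for miR-3156-5p, so the scaling step did not give them their direction. Background correction stays open: with the local background column 12 of the 15 stayed negative, miR-5006-5p with -0.020, and 6 at least 2-fold lower. Whether these probes read the named miRNAs or other RNA fragments of either preparation stays open, since probe sequences were not used here.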

How the results depend on the processing

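The main background correction, without the local background column, was chosen after the data were seen, as were scaling to the spike controls and the random lists of early-registered miRNAs; the local background column was the planned choice, and the other settings were planned. No paired analysis was possible because there was 1 array per group and no test. The log2 differences of miR-155-5p (1.35 to 1.58), miR-146a-5p (1.19 to 1.72) and miR-146b-5p (1.01 to 1.44) kept their direction and stayed above 1 over 15 settings. Their sizes moved by more than the spot-to-spot SD in some, while settings that change only the detection filter could not move them. The numbers of detected miRNAs stayed within 1.5 times the main ones under each limit tried. Of 203 list medians recomputed, the sign changed in 25, over 10 lists, and 23 of these had a main median smaller in size than the spot-to-spot SD of a single difference; the epithelial and neural medians changed sign most often. For single named miRNAs the sign changed in 40 values, 17 of them from a main value under that SD. Signal over background limits the dim probes. The causes of the changes below were not tested, except where a size rule changes a count by its construction.

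With a 1.5-fold size rule 25 miRNAs were higher and 62 lower, 87 in all; with a 3-fold rule 0 and 6, 6 in all. No miRNA detected on 1 array had a bound of at least 2-fold, 0 on the infected and 0 on the non-infected array, while in the deposited values 7 and 13 had one, a count added after the results were seen. With the blank mean subtracted 33 were higher and 48 lower (81 in all), and list medians were -0.51 for the miR-320 family, -0.18 for muscle and -0.70 for endothelial or lymphoid miRNAs. In the authors' deposited values 31 were higher and 54 lower (85 in all), with medians of -0.21 for muscle and -0.69 for endothelial or lymphoid miRNAs. With offset 0 there were 32 in all, 23 of them lower, and the endothelial or lymphoid median was -0.55.

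With arrays centred on their medians 11 were higher, the GC-rich median was 0.35 and miR-1246 turned to 0.079. At the 75th percentile the GC-rich median was 0.28 and miR-1246 turned to 0.0091. Without scaling 15 were higher and 8 lower. Medians were then 0.21 for miRNAs responsive to bacterial ligands, 0.24 for phorbol ester differentiation, 0.22 for let-7, -0.30 for miR-17-92, 0.43 for GC-rich entries and -0.17 for miR-320. The vesicle-associated median turned to 0.018, miR-124-3p to 0.0081 and miR-1246 to 0.15. With only miRNAs above 4 times the limit, medians were 0.48 for miRNAs responsive to bacterial ligands, -0.53 for myeloid-enriched, 0.43 for phorbol ester differentiation, -0.66 for miR-17-92 and -0.36 for vesicle-associated miRNAs.

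With the local background column, as originally planned, 38 were higher and 33 lower (71 in all). Pearson's r was 0.925 and Spearman's rho 0.868, and the endothelial or lymphoid median turned to 0.0063. Among the named miRNAs with a main value of at least the spot-to-spot SD, turned from lower to higher were miR-6131 (3.47), miR-106a-5p (0.73), miR-191-5p (0.52), miR-320b (0.32), miR-1246 (0.27), miR-451a (0.18), miR-320c (0.096), let-7c-5p (0.032), miR-181b-5p (0.019), miR-124-3p (0.016) and miR-5008-3p (0.012). Of the same kind, turned from higher to lower were miR-222-3p (-1.94), miR-107 (-0.79), miR-29a-3p (-0.29), miR-103a-3p (-0.23), miR-29b-3p (-0.19), let-7i-5p (-0.18), miR-125a-5p (-0.048) and miR-142-3p (-0.018). From smaller main values, let-7e-5p turned to -0.22, miR-128-3p to 0.067, miR-126-3p to 0.065, miR-133b to 0.017, miR-133a-3p to -0.012 and miR-205-5p to 0.0077. miR-3135b, at least 2-fold lower in the main values, turned to more than 2-fold higher. Other named miRNAs kept their sign and moved further from 0, such as miR-17-5p (-2.91), miR-21-5p (-2.48), miR-223-3p (-2.38), miR-20a-5p (-2.31) and miR-3197 (3.33).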

Other observations

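The hypotheses in this part were tested after the results were seen. Other miRNA families lay low on the infected array. Families were formed from miRNA names, separately per arm, and 9 had at least 4 members detected on both arrays. Of these, 4 had medians below the middle 95% of matched random lists and none above it. Members of a family are closely related, whereas the random lists were drawn without regard to that, so the percentiles may overstate how unusual a family is. The 5 miR-30-5p members had the lowest median log2 difference of the 9, -0.72, at percentile 0.62. The families were not set against early-registered miRNAs alone. Their values were unequal: miR-30a-5p (-0.78), miR-30d-5p (-0.75) and miR-30e-5p (-0.72) lay well below miR-30b-5p (-0.20) and miR-30c-5p (-0.092). The family median lay between -0.75 and -0.48 in the other settings. The 9 members of the miR-378 family had a median of -0.13 and the 4 miR-181-5p members one of -0.16. Both families were dim, and their medians turned to 0.033 and 0.010 with the local background column. The remaining low family was miR-320, already reported as a list. Its 4 members of this name pattern had a median of -0.34, and of -0.058 with the local background column. The hypothesis that members of a family move together was tested over all 9 families: the mean within-family SD was 0.146, inside the 0.13 to 0.29 of random families matched on signal, so it was not borne out. The miR-30-3p members, for one, ranged from -0.62 to 0.32.

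Among the brightest of 4 equal bins by signal of the miRNAs detected on both arrays, 54 early-registered miRNAs (MIMAT number below 1000) had a median of -0.20 and 446 later ones a median of 0.067. By at least 1.5-fold, 12 of the 54 were lower and 3 higher, against 39 and 21 of the 446. Members of the miR-17-92 list, such as miR-17-5p, miR-20a-5p and miR-106a-5p, are among these 12, so the trend and that list are not separate. The gap between the medians was -0.263, and -0.217 with the local background column, the smallest in size. Shifting an array as a whole leaves such a gap as it is, and the gap prompted the hypothesis that the long-known miRNAs were lower as a class, so that hypothesis stays open. Sequence composition, which differs between old and recent entries, may play a part and was not tested. Without scaling the median of the early miRNAs was 0.023 and that of the later ones 0.31, so which class moved depends on the scale.

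No joint movement of the arms of a hairpin was detected across hairpins. Over 211 hairpins with both arms at or above the median signal, Spearman's rho of the 5p and 3p differences was 0.0859, within the -0.13 to 0.13 that shuffled pairings gave. The hypothesis of joint movement of the arms was therefore not borne out. The miR-142 arms, at -0.61 for miR-142-5p and 0.51 for miR-142-3p, went opposite ways, though miR-142-3p turned to -0.018 with the local background column.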
